A study of Mus musculus with 6 samples.

How the data were processed

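RNA from sorted HSCs of 3 wild type and 3 mutant mouse samples was amplified with a whole-transcriptome kit for small inputs, biotin-labelled and hybridised to Affymetrix mouse gene arrays that read each transcript along its length, per the labels' protocols. The labels call the samples biological replicates, and the p-values of single genes measure the spread between these samples. The authors deposited log2 probe-set signals for 34760 probe sets, between 0.93 and 13.9. The submitters' processing notes name Affymetrix Expression Console. The background correction, summarisation and normalization are not given in the sources used here. That the values are on the log2 scale was read from their range, and signals were not set against background, so a low level is not the absence of a transcript. The number of arrays limits the precision.

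Columns were matched to samples by their labels, and 0 columns were left unmatched. No pair of columns was identical (0 found). The medians of the deposited columns were 4.53, 4.65 and 4.54 in wild type replicates 1 to 3 and 4.53, 4.60 and 4.61 in mutant replicates 1 to 3. Their range of 0.12 was above the limit of 0.1 set beforehand, so the 6 columns were quantile-normalized. The platform annotation gave exactly 1 gene for 21640 probe sets, several for 1321 and none for 11799. Of the first, 21553 matched an NCBI RefSeq gene by Entrez identifier, from which symbols were updated. Probe sets with several genes or none were left out of gene-level results. For the 954 genes with several probe sets, the one with the highest mean over all 6 samples was used, which left 19937 genes. No filter on dim probe sets was applied.

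Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups of 3, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The values after ± are SDs over 3 samples, and SE is limma's standard error of a difference. All log2 differences are mutant minus wild type. Foxm1 was also tested with a two-sided exact permutation test. The 34 gene lists, covering the cell cycle, HSC identity, stress, metabolism, signalling and the other cell types the sort could hold, were compared with all other genes by camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 33 lists with at least 5 measured members. They hold 748 different measured genes, some of them in several lists. Within each list, limma's p-values were also adjusted over the list alone. With the preset correlation, camera's p-values rest mainly on the spread across genes and not on that between samples. fry and camera with an estimated correlation stand beside the main test. The test of the genes and of the lists, the lists themselves, the alternatives other than those named as added, and the rule for named genes were fixed before the data were examined.

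The rule named Foxm1, up to 15 genes in each direction past the threshold, and, where a direction had under 12 of these, the genes of smallest unadjusted p with at least a 1.5-fold change and no overlap between groups, up to 12. It also named up to 4 members of each list described, by unadjusted p, and 12 genes tied to FOXM1 or HSC quiescence. It gave 79 genes, 77 of them measured. Genes outside the rule are said to have been named after their values were seen.

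The gene test was tested on simulated data for this comparison, drawn for the same 19937 genes, with 50 genes changed at each fold. It recovered 12% of the genes changed 2-fold, 94% at 4-fold, 96% at 8-fold and 100% at 16-fold, with 7 false calls. The list test called 2 of 2 simulated lists shifted by a log2 value of 0.5 and 0 others of the 33. Both simulations drew the noise independently for each gene and sample. They held no structure of samples and no correlation between genes. The genes of all folds were changed together, which loosens the Benjamini-Hochberg adjustment for each of them. In the measured data, where no gene was called, a gene needed a smaller unadjusted p to pass. The shares may therefore overstate what the tests recover in the measured data. There, Snord14e and Dnajb9 had log2 differences of 4.37 and -2.83 and did not pass over all genes. The absence of called genes thus does not show the absence of large changes.

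Alternatives were no normalization, median centring, filters on dim genes (above the median level, or the top 80 percent), the mean of a gene's probe sets, an intensity trend with robust variances, array weights, the replicate number as a block, camera with an estimated correlation or on ranks, an adjusted p under 0.1, an unadjusted p with a 1.5-fold change, and leaving out each sample in turn. Added after seeing the data were a block for samples of high and low deposited median, called the signal-median block, and the lists without their leading members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.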

Results

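Genome-wide transcript levels were measured in hematopoietic stem cells (HSCs) sorted from the bone marrow of 2-month-old C57BL/6 mice. HSCs are the self-renewing cells from which all blood lineages descend. The sort kept cells without lineage markers that carried Kit, Sca-1 and CD150 and lacked CD48. Of the 6 samples, 3 came from mice with floxed Foxm1 alleles and no Cre (wild type), and 3 came from mice that also carried the Tie2-Cre transgene. These last 3 are the samples labelled Foxm1 mutant, called mutant here. Tie2-Cre is active in endothelial cells and in blood-forming cells. Each sample was hybridised to 1 array, on which 19937 genes had a probe set of their own. Pearson correlations between samples, across genes, ranged from 0.906 to 0.939 within groups and from 0.904 to 0.939 between groups. Wild type replicate 2 had the lowest mean correlation with the other samples, 0.906, and lay apart from them on the first principal component, which held 27.1% of the variance. It had 34 genes at least 4-fold below every other sample, among them Cd48 and, named after their values were seen, Cox5b, Cyc1, Bub1 and Prim1, against 16 in mutant replicate 3, 8 in mutant replicate 2 and 1 to 5 in the other samples.

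The comparison addressed how the HSC transcriptome differs when Foxm1 is targeted. Foxm1 encodes a forkhead transcription factor known for driving genes of the G2 and M phases of the cell cycle. Its probe set read 6.19, 4.43 and 6.04 (log2 signal) in wild type replicates 1 to 3 and 5.34, 5.97 and 5.18 in mutant replicates 1 to 3. The group means were 5.55 ± 0.98 and 5.49 ± 0.42 (SD, n = 3 each), a log2 difference of -0.06 with a 95% interval from -1.25 to 1.13. A two-sided exact permutation test gave p = 0.9, where the smallest p that 3 against 3 samples allow is 0.1. The probe set covers the whole transcript, exons outside a floxed part included, so the values neither check nor contradict the genotype labels. The difference was -0.62 without wild type replicate 2, which had the lowest value. Leaving out wild type replicate 1, wild type replicate 3, mutant replicate 1 or mutant replicate 3 turned the sign of the difference, to 0.26, 0.19, 0.02 and 0.10.

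No single gene passed the test over all genes, and 4 lists of genes were called by camera with a preset correlation between genes. The list of NR4A receptors and immediate early genes was called lower in mutant than in wild type HSCs, with 17 of 23 members lower. These genes encode transcription factors and regulators induced within minutes of a stimulus. The means of single samples over this list overlapped between the groups. The unfolded protein and heat shock list was also called lower, with 15 of 27 members lower and Dnajb9 at its head. The lists of nuclear oxidative phosphorylation genes and of genes of multipotent progenitors, the offspring of HSCs, were called higher, with 36 of 49 and 12 of 15 members higher. None of the 4 calls held with an estimated correlation or on ranks, and each was lost on leaving out either of 2 samples, which are named with each list. The estimated correlation was 0.20 for the immediate early list and 0.06 for oxidative phosphorylation. It was 0.02 for the progenitor list and -0.02 for the unfolded protein list. In the last it lay below the preset 0.01, yet camera's unadjusted p rose from 0.0013 to 0.023. Correlation between its members was thus not what undid that call.

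Of the 23 measured immediate early genes, 17 were lower and 6 higher in the mutant samples, with a median log2 difference of -0.22 and a mean of -0.33. Each sample's mean over the list was taken relative to the members' means over all 6 samples. It was 0.24, 0.30 and -0.04 in wild type replicates 1 to 3. In mutant replicates 1 to 3 it was -0.04, 0.05 and -0.50, so the groups overlapped. The camera adjusted p was 0.0219, and the adjusted p = 0.729 with an estimated correlation. None of the 23 passed limma's test, adjusted over the list alone or over all genes. Nr4a2, an orphan nuclear receptor, had a mean of 8.67 ± 0.29 in wild type and 7.12 ± 0.63 in mutant HSCs, a log2 difference of -1.55 (SE 0.34). Maff, a small MAF transcription factor, and Atf3, a stress-induced transcription factor, had log2 differences of -1.18 and -1.22. Rhob, a small GTPase, went the other way, with a log2 difference of 0.87. The related receptors Nr4a1 and Nr4a3 and the AP-1 subunit Fosb, named after their values were seen, had log2 differences of -1.96, -0.41 and -0.66. Nr4a2 was, as remembered, put forward by the study itself, so the list is not independent evidence of its direction. Without the 3 NR4A genes, an alternative chosen after seeing the data, the list's adjusted p was 0.183. It was 0.149 without wild type replicate 1 and 0.280 without mutant replicate 3.

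**Figure D1:**
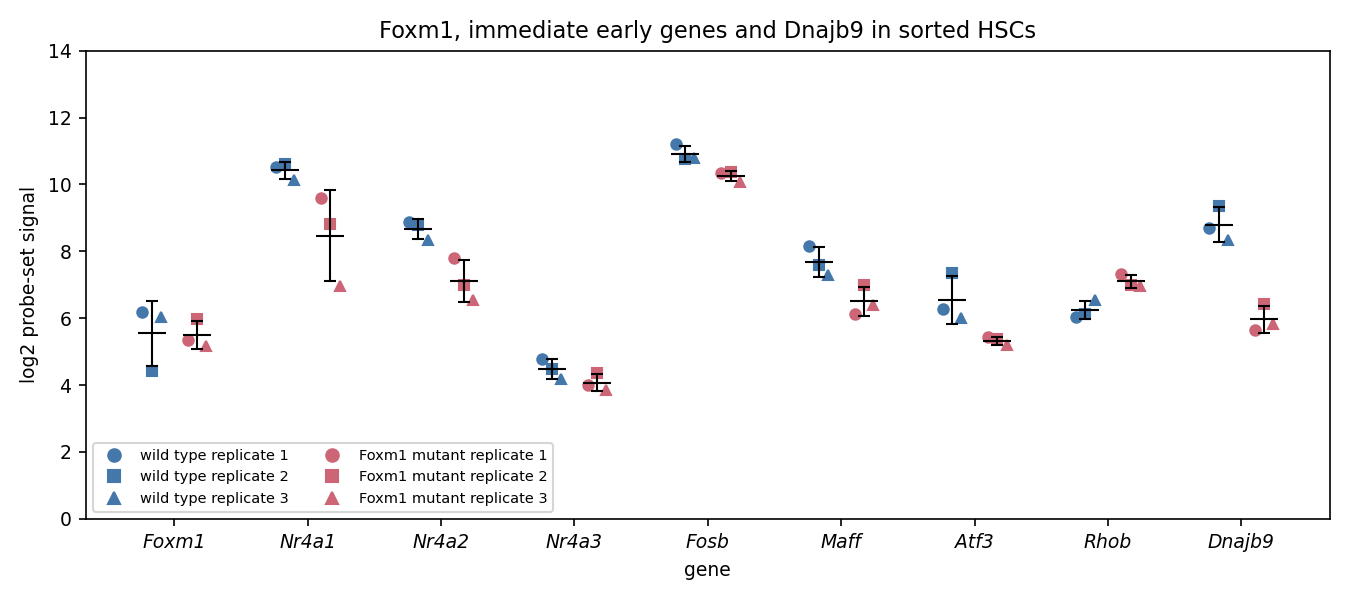
Log2 probe-set signal (vertical axis) of Foxm1, 7 immediate early genes and Dnajb9 (horizontal axis) in each sample. Symbols are single arrays, and black bars are the mean ± SD of 3 samples. Dnajb9 and Nr4a2 lay lower in all 3 mutant samples than in all 3 wild type samples, while Foxm1 overlapped; none of these genes passed the test over all genes.

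Of the 27 measured genes of the unfolded protein and heat shock response, 15 were lower and 12 higher in the mutant samples, with a median log2 difference of -0.12 and a mean of -0.29. The relative sample means over the list were 0.16, 0.08 and 0.19 in wild type replicates 1 to 3. They were -0.14, -0.21 and -0.08 in mutant replicates 1 to 3. The camera adjusted p was 0.0219, and the adjusted p = 0.643 with an estimated correlation. Dnajb9, a co-chaperone of the endoplasmic reticulum induced by unfolded proteins, led the list. Its mean was 8.80 ± 0.53 in wild type and 5.97 ± 0.41 in mutant HSCs, a log2 difference of -2.83 (SE 0.33). It passed limma's test adjusted over the list alone (adjusted p = 0.00227), but not over all genes (adjusted p = 0.558). The adjustment over a list alone takes no account of the number of lists. Across all lists 3 members passed in this way, Dnajb9 and, in lists given below, Prtn3 and Nkg7. The chaperone Hsp90b1, the stress sensor Atf6 and the transcription factor Atf4 had log2 differences of -0.53, -0.94 and -0.59 (Atf4 -0.35 without mutant replicate 3). The list held members that went the other way, among them the chaperone Hspa5 (0.25), named after its value was seen. Without Dnajb9, an alternative chosen after seeing the data, the list's adjusted p was 0.0869. It was 0.149 without wild type replicate 1 and 0.111 without mutant replicate 2. With the signal-median block, also chosen after seeing the data, it was 0.0925.

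Of the 49 measured nuclear genes of oxidative phosphorylation, 36 were higher and 13 lower in the mutant samples, with a median log2 difference of 0.25 and a mean of 0.24. The relative sample means over the list were -0.081, -0.301 and 0.025 in wild type replicates 1 to 3. They were 0.002, 0.063 and 0.291 in mutant replicates 1 to 3, so the groups overlapped. The camera adjusted p was 0.0224, and the adjusted p = 0.643 with an estimated correlation. None passed limma's test adjusted over the list alone. Cox7a2, a subunit of cytochrome c oxidase, had means of 6.33 ± 0.19 in wild type and 7.19 ± 0.13 in mutant HSCs, a log2 difference of 0.86 (SE 0.17). Atp5c1, a subunit of ATP synthase, had a log2 difference of 0.92, and the complex I subunits Ndufa10 and Ndufs8 had 0.95 and 0.74. Wild type replicate 2 had low values in some members. Cox5b, named after its values were seen, read 4.69 there and between 7.30 and 8.73 in the other samples. The list's adjusted p was 0.445 without wild type replicate 2 and 0.246 without mutant replicate 3. It was 0.0579 with an intensity trend and robust variances, and 0.0884 with array weights.

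Of the 15 measured multipotent progenitor genes, 12 were higher and 3 lower in the mutant samples, with a median log2 difference of 0.38 and a mean of 0.46. The relative sample means over the list were -0.478, -0.138 and -0.0815 in wild type replicates 1 to 3. They were 0.612, -0.0806 and 0.166 in mutant replicates 1 to 3, so the groups barely parted. The camera adjusted p was 0.0290, and the adjusted p = 0.643 with an estimated correlation. None passed limma's test adjusted over the list alone. Cd48, the surface antigen that the sort excludes, had means of 6.01 ± 2.04 in wild type and 7.80 ± 0.91 in mutant HSCs, a log2 difference of 1.79 (SE 1.01). Its single values were 7.24, 3.66 and 7.14 in wild type replicates 1 to 3 and 8.15, 6.77 and 8.50 in mutant replicates 1 to 3. Dntt, the DNA polymerase of lymphoid progenitors, had a log2 difference of 1.01, the interleukin receptor gene Il7r 0.38 and the chemokine receptor gene Ccr9 0.25. Il7r had means of 3.14 in wild type and 3.52 in mutant HSCs, and Ccr9 of 3.43 and 3.69. These levels lie near the lower quartiles of the deposited arrays (3.41 to 3.55), so the 2 differences are uncertain. Single samples carried much of the values of Dntt and Cd48: Dntt had 0.18 without mutant replicate 1, and Cd48 had 0.62 without wild type replicate 2. Cd52, named after its values were seen, read 4.62 in wild type replicate 1 and between 7.06 and 9.26 in the other samples. The list's adjusted p was 0.149 without wild type replicate 1 and 0.414 without mutant replicate 1. Without its members that are also granulocyte markers, an alternative chosen after seeing the data, it was 0.0775. With the filters on dim genes it was 0.107 in the top 80 percent and 0.170 above the median level.

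**Figure D2:**
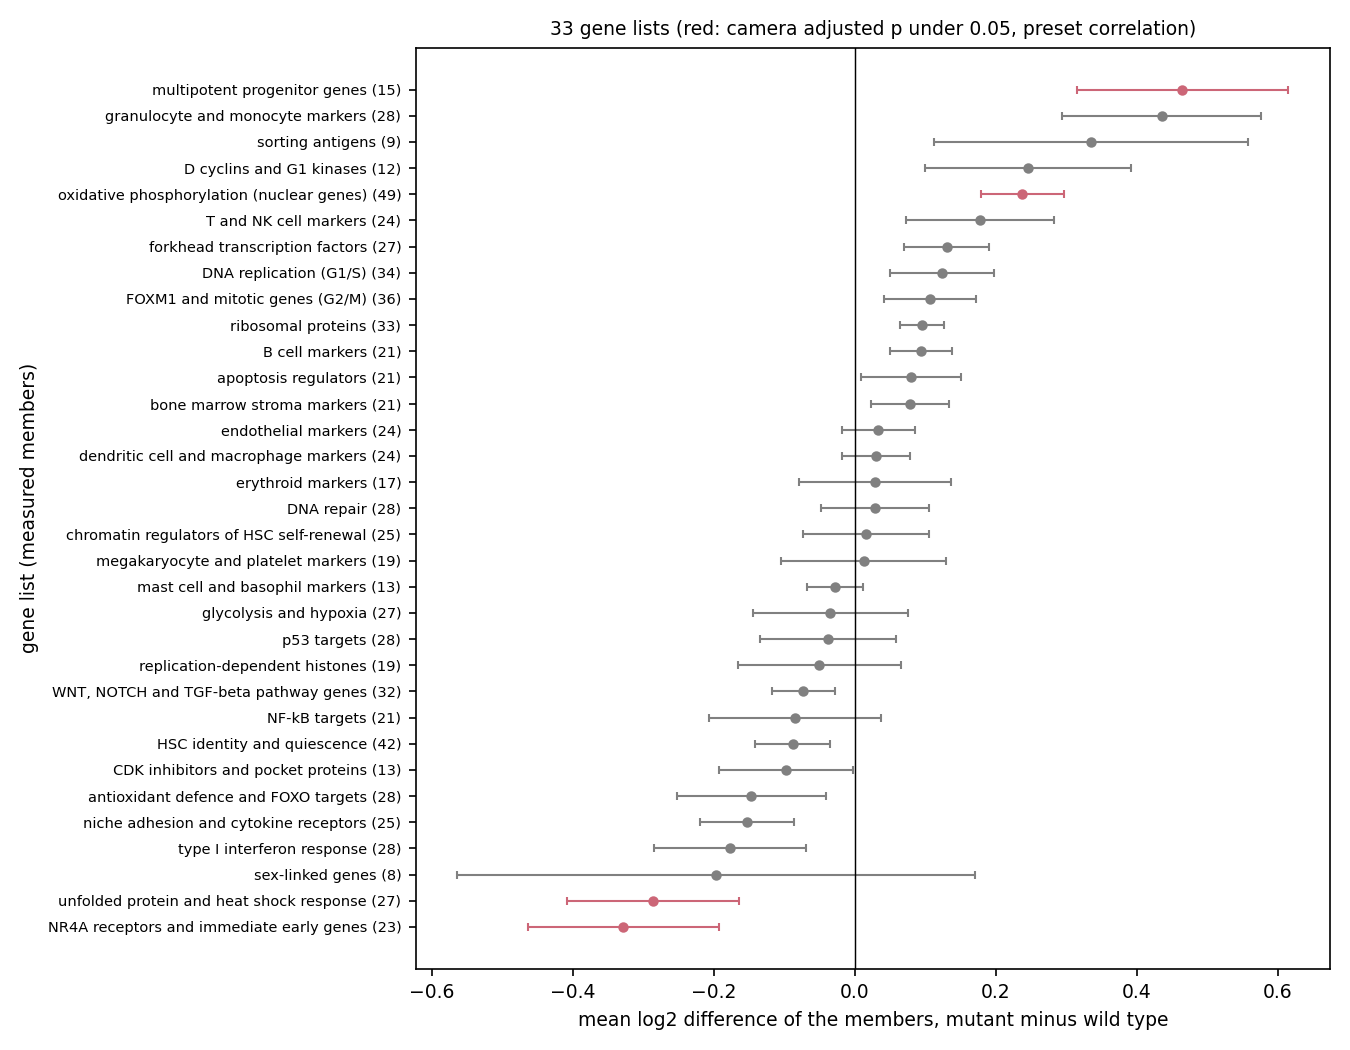
Mean log2 difference of the members, mutant minus wild type (horizontal axis), for the 33 gene lists with at least 5 measured members (vertical axis, number of members in brackets). Bars are the SD of the members' differences divided by the square root of their number, across genes, which are not independent replicates. The 4 lists in red, at mean differences of -0.33, -0.29, 0.24 and 0.46, had a camera adjusted p below the threshold.

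The targets of FOXM1 were examined through the list of FOXM1 and mitotic genes. Of its 36 measured members, 25 were higher and 11 lower in the mutant samples, with a median log2 difference of 0.04 (camera adjusted p = 0.534). Cdca8, a subunit of the chromosomal passenger complex, had a log2 difference of 1.23, and the mitotic phosphatase gene Cdc25c had 0.44. It was -0.67 for the mitotic kinesin gene Kif20a and -0.41 for Skp2, which targets CDK inhibitors for degradation. In other genes tied to FOXM1 it was 0.48 for Plk1, 0.01 for Aurkb, -0.74 for Cenpf, 0.04 for Cdc25b and -0.25 for the proliferation marker Mki67, and none of these passed limma's test. Kif20a had -0.15 and Cenpf -0.41 without wild type replicate 3, and Cdc25c had 0.21 without mutant replicate 2. The sign turned for Plk1 (-0.06 without mutant replicate 1), Mki67 (0.07 without mutant replicate 2) and Aurkb (-0.11 without mutant replicate 2). The list was called higher without mutant replicate 2 (adjusted p = 0.00746) and with the signal-median block, chosen after seeing the data (adjusted p = 0.0250). Its direction turned without wild type replicate 2 (adjusted p = 0.504) and without mutant replicate 1 (adjusted p = 0.564). Ccnb1 was not analysed here, because no probe set names it alone.

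Other cell cycle groups did not pass the test either. Of the 34 measured genes of DNA replication, 20 were higher and 14 lower (median log2 difference 0.04, adjusted p = 0.694). Cdc45, Mcm2 and Mcm7, parts of the replicative helicase, had log2 differences of 1.24, 0.51 and -0.49, and Rrm1, a subunit of ribonucleotide reductase, had 1.12 (0.56 without wild type replicate 2). Of 12 D cyclins and G1 kinases, 9 were higher (median 0.18, adjusted p = 0.110). Log2 differences were 1.24 for Cdk4, 0.69 for Ccnd3, 0.52 for Ccnd1 and 0.52 for Mycn, with Ccnd3 at 0.45 without mutant replicate 2 and Ccnd1 at 0.27 without mutant replicate 1. This list was called higher without mutant replicate 3 (adjusted p = 0.0205) and with the signal-median block, chosen after seeing the data (adjusted p = 0.0298). Of 13 CDK inhibitors and pocket proteins, 6 were higher and 7 lower (median -0.03, adjusted p = 0.694). The log2 difference was -0.75 for the antiproliferative gene Btg1, -0.43 for Btg2, 0.29 for Cdkn2d and -0.48 for Cdkn2c. It was -0.39 (SE 0.47) for Cdkn1b and 0.19 (SE 0.20) for Cdkn1c. Without mutant replicate 3, Cdkn2c had -0.12 and Cdkn2d 0.14. Btg2 had -0.26 without wild type replicate 1, Cdkn1c 0.07 without mutant replicate 2, and Cdkn1b turned to 0.13 without wild type replicate 2. Cdkn1a, which the study, as remembered, also put forward, was not analysed here, because no probe set names it alone.

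Neither the HSC identity genes nor the niche genes passed the test as a group. Of 42 HSC identity and quiescence genes, 17 were higher and 25 lower (median log2 difference -0.07, adjusted p = 0.244). Mycn, which had the smallest unadjusted p of the list, had a log2 difference of 0.52. Hoxb4, Mllt3 and Egr1, transcriptional regulators of HSC maintenance, had log2 differences of -0.32, -0.30 and -0.41 (Egr1 -0.24 without mutant replicate 3). Of 25 niche adhesion and cytokine receptor genes, 8 were higher and 17 lower (median -0.18, adjusted p = 0.0879). The log2 difference was -0.44 for the tetraspanin gene Cd9, -0.65 for the adhesion molecule gene Alcam, -0.49 for the junctional adhesion gene Jam3 and 0.93 for the chemokine receptor gene Cxcr4. Jam3 had -0.13 without wild type replicate 3 and Cxcr4 0.30 without wild type replicate 2. The niche list was called lower without wild type replicate 2 (adjusted p = 0.0129) and without mutant replicate 1 (adjusted p = 0.0239).

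Markers of other blood cells were measured because the sort could hold them. Of 28 granulocyte and monocyte markers, 21 were higher and 7 lower in the mutant samples (median log2 difference 0.19, adjusted p = 0.106). Prtn3, a neutrophil granule protease, passed limma's test adjusted over the list alone (adjusted p = 0.0458), with means of 5.42 ± 0.14 in wild type and 6.26 ± 0.14 in mutant HSCs, and not over all genes. Elane, another granule protease, had a log2 difference of 1.36, with 0.52 for the transcription factor Irf8 and 0.40 for the Fc receptor gene Fcgr3. Without mutant replicate 1, Elane had 0.82 and Fcgr3 0.21. Abundant granulocyte transcripts were far lower in wild type replicate 1 than in the other samples. S100a8, which encodes an abundant protein of neutrophils, read 5.69 there and between 11.9 and 12.2 in the other 5 samples. The granulocyte list turned lower without wild type replicate 1 (adjusted p = 0.939). It was called higher without wild type replicate 2 (0.0487), wild type replicate 3 (0.0154) or mutant replicate 2 (0.00780). Of 24 T and NK cell markers, 18 were higher and 6 lower (median 0.13, adjusted p = 0.106). Nkg7, a gene of cytotoxic granules, passed adjusted over the list alone (adjusted p = 0.0118), with means of 5.63 ± 0.34 and 8.03 ± 0.70, and not over all genes (0.983). Thy1, Cd8a and Cd3d, all T cell antigens, had log2 differences of 0.31, 0.35 and 0.28. Cd3d had means of 3.03 in wild type and 3.31 in mutant HSCs. Both lie below the lowest lower quartile of the deposited arrays (3.41), so its difference is uncertain. The T and NK cell list was called higher without wild type replicate 2 (adjusted p = 0.0353).

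**Figure D3:**
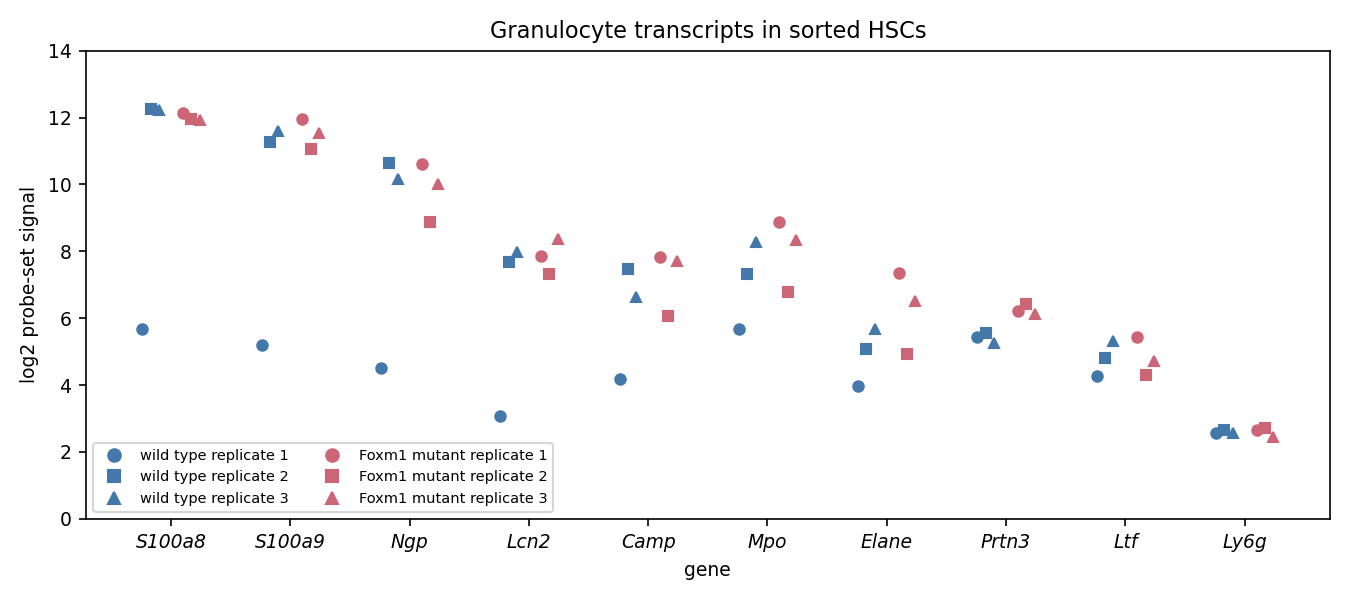
Log2 probe-set signal (vertical axis) of 10 granulocyte genes (horizontal axis) in each of the 6 samples, 1 symbol per array. S100a8 read 5.69 in wild type replicate 1 and at least 11.9 in the other 5 samples, while Ly6g lay between 2.44 and 2.72 in all 6.

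Among single genes, limma called 0 at an adjusted p under 0.05, and the lowest adjusted p was 0.265. At an unadjusted p under 0.05 there were 807 genes, 409 higher and 398 lower in mutant HSCs, where chance gives 997. The 3 values of one group all lay beyond the 3 of the other in 1795 genes, 9.0%, where chance gives 10%. The values that follow are of genes that did not pass the test. Npc2, which moves cholesterol out of lysosomes, had means of 8.55 ± 0.08 in wild type and 6.95 ± 0.14 in mutant HSCs, a log2 difference of -1.60 (SE 0.15, adjusted p = 0.265). Other genes lower in all 3 mutant samples included Ncoa4 (-1.74, or -0.93 with the mean of its 2 probe sets), the receptor for the breakdown of ferritin, Vps41 (-1.60) and Eea1 (-1.74), which act in endosome fusion, and Dennd1b (-1.43), which activates Rab GTPases. Zpr1, Sh3bgrl, Mri1, Abhd16b, the RNA uridylyltransferase gene Tut7 and the histone gene H2bc8 had log2 differences between -1.11 and -0.75. Among genes higher in all 3 mutant samples, the log2 difference was 1.45 for Acadm, an enzyme of fatty acid oxidation, 1.86 for Atp6v1b2, a subunit of the vacuolar proton pump, and 2.32 for the telomere protein gene Terf1. It was 1.46 for Utp14a, 1.94 for Pagr1a and 3.01 for A630089N07Rik. Prxl2a, Lime1, Flot2 and Tfpt had log2 differences between 0.82 and 1.31. Snord14e had the largest difference of the named genes, from 4.57 ± 0.70 to 8.94 ± 0.50 (log2 difference 4.37, adjusted p = 0.265). It encodes a small nucleolar RNA with close copies in the genome, so the value is uncertain.

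Besides camera, fry, which asks whether a list's genes move on balance one way, called 0 of the 33 lists (lowest adjusted p = 0.295). Its test for change in either direction called 2, the unfolded protein and heat shock response (adjusted p = 0.00652) and the T and NK cell markers (adjusted p = 0.0149).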

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

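The signal-median block and the lists without the NR4A genes, without Dnajb9 or without granulocyte members were chosen after the results were seen, as were the splits. limma called 0 genes in the main setting and under all 15 refits with another normalization, filter, weight, block or set of samples, and 0 at an adjusted p under 0.1; an unadjusted p with a 1.5-fold change gave 552. Genes higher by 1.5-fold at an unadjusted p went from 266 to 410 without mutant replicate 1 and 424 with the signal-median block, and lower ones from 286 to 473 without wild type replicate 2. Among genes above the median level, 208 were higher and 224 lower at an unadjusted p, against 409 and 398, with fewer genes tested. Of the 10 splits of the 6 samples into 3 and 3, 6 gave as many genes at an unadjusted p (real 807, highest other 1982), 6 with a 1.5-fold change (552 against 1080) and 3 as many called lists (4 against 6). At an adjusted p under 0.05 the real count of 0 (highest other 0) is matched by all 10 by construction, so the splits test nothing there. Of the 9 other splits, 2 called the immediate early list, 2 oxidative phosphorylation, 0 the unfolded protein list and 0 the progenitor list. So few splits cannot give a share under 0.05. The replicate numbers did not pair the samples: deviations of equally numbered samples correlated at 0.08, 0.04 and -0.06, and only replicate 1 matched best with its own number. With the replicate block, 0 genes and 4 lists were called, and the only turned direction was that of the chromatin regulators (adjusted p = 0.939).

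The 4 lists became 0 with an estimated correlation and 0 with ranks, and 1 to 7 when 1 sample was left out, with 1 without wild type replicate 1 and 7 without wild type replicate 2. With ranks the adjusted p was 0.0901 for the immediate early genes, 0.0512 for the multipotent progenitor genes, 0.0512 for oxidative phosphorylation and 0.138 for the unfolded protein response; with an estimated correlation it was 0.729, 0.643, 0.643 and 0.643. Leaving out 1 sample gave 0.00246 to 0.280, 0.0124 to 0.414, 0.00246 to 0.445 and 0.00267 to 0.149. The immediate early list had 0.183 without the NR4A genes. The progenitor list had 0.170 among genes above the median level, 0.107 in the top 80 percent and 0.0775 without members of the granulocyte list. Oxidative phosphorylation had 0.0579 with trend and robust variances and 0.0884 with array weights. The unfolded protein list had 0.0869 without Dnajb9 and 0.0925 with the signal-median block. Under the signal-median block the G2/M list was called higher (0.0250); with array weights it turned lower (0.964), as did the DNA replication list (0.969). Further lists called were the granulocyte (0.0317) and T and NK cell markers (0.0317) among genes above the median level, the T and NK cell (0.0442) and niche lists (0.0289) with array weights, ribosomal proteins (0.00328) with the mean of the probe sets, and ribosomal proteins (0.0311) and D cyclins (0.0298) with the signal-median block. The causes were not tested.

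Foxm1's difference was 0.19 with the signal-median block and ranged from -0.62 to 0.26 with 1 sample left out. Under such omission Cdkn1b ranged from -0.76 to 0.13 (0.19 with the mean of its probe sets), Mki67 from -0.43 to 0.065, Plk1 from -0.058 to 0.89 and Aurkb from -0.11 to 0.14. Lists that turned direction when 1 sample was left out had adjusted p ranges of 0.00746 to 0.742 (G2/M), 0.191 to 0.856 (DNA replication), 0.378 to 0.983 (erythroid), 0.602 to 0.957 (megakaryocyte), 0.00780 to 0.939 (granulocyte), 0.434 to 0.957 (mast cell), 0.775 to 0.983 (endothelial), 0.808 to 0.957 (p53), 0.193 to 0.941 (NF-kB), 0.179 to 0.861 (DNA repair), 0.0360 to 0.957 (ribosomal), 0.361 to 0.910 (glycolysis), 0.775 to 0.941 (chromatin) and 0.775 to 0.983 (sex-linked). Among genes above the median level, p53 targets (0.922) and DNA repair (0.456) turned. With the signal-median block, p53 targets (0.958), DNA repair (0.567), glycolysis (0.871), antioxidant genes (0.875) and chromatin regulators (0.898) did, and glycolysis did with ranks (0.934). None of these turned values was past the threshold. All other measured named genes kept their direction in every setting run.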

Other observations

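All tests of explanations in this part were chosen after the results were seen, while the gene lists were fixed beforehand. Markers of most other cell types gave no called difference between mutant and wild type HSCs. The camera adjusted p was 0.534 for 21 B cell markers (median log2 difference 0.02), 0.901 for 17 erythroid markers (-0.04), 0.901 for 19 megakaryocyte and platelet markers (-0.002), 0.709 for 13 mast cell and basophil markers (-0.008), 0.694 for 24 dendritic cell and macrophage markers (0.07), 0.901 for 24 endothelial markers (-0.03) and 0.534 for 21 bone marrow stroma markers (0.06). It was 0.352 for 9 antigens of the sort (0.18). Sex-linked genes (8 measured, median 0.15, adjusted p = 0.901) parted 1 sample from the rest. Xist, the RNA of the inactive X chromosome, read 11.3 in wild type replicate 3 and between 3.14 and 3.78 in the other 5 samples, while the Y-linked Eif2s3y read 2.89 there and between 5.72 and 7.48 in the others. These levels point to female cells in wild type replicate 3 and male cells in the other 5 samples. The labels do not give the sex. The sexes would then be mixed in the wild type group alone, and no fit held sex as a covariate. The fit without wild type replicate 3 left only samples with male levels. In it limma called 0 genes, and camera still called the 4 lists. Their adjusted p was 0.00246 for the immediate early genes and oxidative phosphorylation, 0.0300 for the progenitor genes and 0.0360 for the unfolded protein list. Those calls thus did not depend on the sample with female levels.

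Signalling, stress and chromatin lists also stayed above the threshold. The adjusted p was 0.247 for the type I interferon response (28 genes, median -0.10), 0.901 for p53 targets (28, -0.001), 0.694 for NF-kB targets (21, 0.03), 0.901 for DNA repair (28, -0.05), 0.534 for apoptosis regulators (21, 0.06), 0.534 for antioxidant defence and FOXO targets (28, -0.14) and 0.534 for WNT, NOTCH and TGF-beta genes (32, -0.10). It was 0.198 for ribosomal proteins (33, 0.08), 0.198 for forkhead factors (27, 0.16), 0.939 for glycolysis and hypoxia (27, -0.09), 0.901 for chromatin regulators (25, 0.02) and 0.694 for replication-dependent histones (19, -0.01). The interferon list was called lower without wild type replicate 2 (0.0338), and ribosomal proteins were called higher without wild type replicate 3 (0.0360). Only 2 mitochondrially encoded genes were measured, too few for the test, with a median of -0.01. Mean and median differed in sign in 6 lists (NF-kB, DNA repair, erythroid, endothelial, megakaryocyte and sex-linked), mean and test in 4 (DNA repair, endothelial, chromatin, sex-linked) and median and test in 4 (NF-kB, erythroid, megakaryocyte, chromatin). Among the 13120 probe sets without a single named gene, limma called 0 (lowest adjusted p = 0.0590), with 632 at an unadjusted p under 0.05.

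Granulocyte transcripts were low in wild type replicate 1, where S100a8 read 5.69, S100a9 5.21, Ngp 4.53, Lcn2 3.07 and Camp 4.19, against means of 12.1, 11.5, 10.1, 7.84 and 7.13 in the other 5 samples; levels this low were not set against background, so no fold is given. Of the 5 genes of this sample at least 4-fold below every other sample, only Cd52 lay outside the granulocyte list. The 4 inside it are genes of the pattern itself, so their share is no separate evidence. That only 1 other gene was so low argues against widespread random loss of transcripts in the amplification of this sample. Wild type replicate 2 had 34 such genes and mutant replicate 3 had 16, none of them in that list. A loss limited to the transcripts of the pattern was not tested. Granulocyte RNA in the other 5 samples stays open, since the 23 members of the list other than S100a8, S100a9, Ngp, Lcn2 and Camp had a median 0.47 log2 units higher in the other 5 samples, but the same median for mutant replicate 2 against its others was 0.37, and the SD over those samples was 0.18. Of these 23 members, 19 were higher in the mean of the other 5 samples than in wild type replicate 1, and 4 were lower. A Gr1 antibody in the sort would remove granulocytes, and progenitors also express members such as Mpo and Elane. Ltf, Retnlg, Mmp8 and Ly6g stayed between 2.44 and 5.44 in every sample. Ltf (4.28) and Retnlg (3.67) were lowest in wild type replicate 1, while Mmp8 and Ly6g were not. The last 2 lay below the arrays' lower quartiles in every sample, so they show little either way. A difference in the wild type mouse itself stays open, untested.

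The lower immediate early genes in mutant HSCs may come from the genotype or from harsher handling of the wild type cells, which induces such genes too. The genotype joins Foxm1 targeting with the Tie2-Cre transgene, which the wild type mice lacked and which is also active in endothelial cells. Effects of Foxm1 in HSCs, of its targeting in endothelial cells and of the transgene itself cannot be told apart. The 20 members other than the NR4A genes had a median log2 difference of -0.15, with a 95% bootstrap interval across genes from -0.42 to 0.05 (14 lower, 6 higher). The interval includes 0, but an interval below 0 would not have separated genotype from handling either, since both allow lower values in these genes. It also measures a spread across genes and not between samples. Handling therefore cannot be told apart from genotype for this list. A grouping of samples unrelated to genotype also stays open, since 2 of the 9 other splits of the samples called this list.

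The split that joins wild type replicates 1 and 3 with mutant replicate 1 gave 1982 genes at an unadjusted p under 0.05, against 807 between genotypes and at most 941 in the other splits, which points to a structure of the samples. The deposited medians of the 2 sets did not overlap (gap 0.053 log2 units), which is consistent with a difference in the breadth of signal between arrays, though 1 of 10 splits would match by chance. Genes at least 4-fold below every other sample numbered 5, 3 and 1 in wild type replicates 1 and 3 and mutant replicate 1. In wild type replicate 2 and mutant replicates 2 and 3 they numbered 34, 8 and 16. The former samples correlated with each other at 0.939, the latter at 0.904 to 0.916. The latter thus resembled each other no more than they did the rest. Array or RNA quality was not tested as a source of the split. Granulocyte RNA did not part the sets by itself. The mean of 5 granulocyte genes was 4.54 in wild type replicate 1, 9.72 in wild type replicate 3 and 10.1 in mutant replicate 1. It lay between 9.06 and 9.90 in the other set, so the sets overlapped. Without wild type replicate 1 it differed by 0.29 log2 units between the sets, within the SD of 0.42 inside them. A smaller contribution was left open, since 5 samples are too few to decide. With this structure as a block, limma called 0 genes and camera called 6 lists; the labels give no batch, and beyond granulocyte RNA no biological explanation was tested.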
